A study of Mus musculus with 2 samples.

How the data were processed

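Forebrain of mouse embryos at embryonic day 12.5 was profiled by ChIP-seq for H3K9ac in 1 group of 2 biological replicates, per the labels. Replicate 1 was a pool of 120 embryos and replicate 2 a pool of 68, with chromatin sheared to fragments of 300 to 500 bp. Groups and replicate numbers came from the labels. Fragments of that size set the resolution of a peak, so positions finer than a few nucleosomes are not interpreted.

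The authors deposited peak lists on mm10 in place of reads: a list for each replicate, called on that replicate's alignment with its own control alignment, a pooled list called on both alignments with both controls, and a replicated list derived from the other lists, per the deposited file notes. The aligner, the peak caller, their versions and the rule for the replicated list are not given in the sources used here. Each deposited peak has a fold enrichment, a ratio that was read as enrichment over control from the column's place in the format. Each deposited peak also has a −log10 p and a −log10 q, and the values show no −log10 p under 2 in any list. The score the authors deposited for each peak is a display value and was not used. The lists are permissive: q was above 0.05 for 12.8% of peaks of replicate 1, 9.85% of replicate 2, 10.5% of pooled and 0.287% of replicated peaks. Because the replicates had different controls, and a deeper library yields more and weaker peaks, a peak present in a single list can reflect calling as well as the tissue. Read depth is unknown, so no interval on peak height was computed.

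Gene lists, tests, thresholds, the naming rule and the alternatives were fixed before the data were examined, except alternatives and tests said to be chosen later. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Peaks on unplaced scaffolds (10 in each replicate, 13 pooled, 8 replicated) were left out, and coordinates are 1-based. Annotation was GENCODE vM21 on GRCm38, the build named mm10, with 21911 protein-coding gene symbols and 132629 distinct TSSs of all genes. A gene was marked when a replicated peak overlapped the window of 1 kb on either side of any of its TSSs. Replicate overlap asked for at least 50% of the shorter peak, and chance was set by 100 circular shifts along each chromosome that skipped the first 3000000 bp. Domains joined peaks over gaps of up to 1 kb. Distal peaks lay over 2.5 kb from every TSS and were counted within 100 kb of a gene's most 5′ TSS. The marked TSS of a gene, such as Nfib or Gse1, can therefore lie outside that window. A promoter was CpG-rich with an observed to expected CpG ratio of at least 0.6 and GC of at least 55% over 1000 bp around the most 5′ TSS.

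The 24 gene lists were forebrain identity, dorsal telencephalon, ventral telencephalon, diencephalon and hypothalamus, neural progenitor, early neuron, late neuron and synapse, astrocyte and oligodendrocyte, midbrain with hindbrain and spinal cord, HOX, retina and eye, choroid plexus, erythroid, endothelial, microglia and myeloid, mesenchyme (with meninges and pericytes), muscle, liver, pluripotency and germline, olfactory receptors, ribosomal proteins, cell cycle, patterning signals, and histone acetylation. Some genes are in several lists, and 1 listed symbol was not in the annotation. Lists were tested for TSS peaks with Fisher's exact test, two-sided, and for mean log2 domain length and mean number of distal peaks among marked genes with two-sided permutation tests of 100000 draws. Olfactory receptors, with 1 marked gene, were left out of the permutation tests. P-values were adjusted by Benjamini-Hochberg over the lists, with a threshold of 0.05. These tests treat genes as units within a single tissue profile and say nothing of variation between embryos. Genes of a list can share a domain, such as Rpl13a and Rps11, or lie in a cluster, as HOX genes do. Such genes are not independent, so p-values can be too small. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

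The genes named were the 20 with the longest domains, up to 4 marked members of each list with the longest domains and up to 3 unmarked members in alphabetical order (all where there were 5 or fewer), the 5 genes with most distal peaks, the genes at the 5 strongest peaks, and the 5 genes with the longest domain in each replicate alone. Alternatives changed the peak threshold, the peak list, the TSS window and choice, the minimum overlap, the joined gap, the distal limits and the background, and left out each replicate by using the other's own list. The tests were tested on simulated data, except the sequence word test and the count expected from promoter classes. In 50 simulations of TSS peaks, 98.7% of lists with a planted odds ratio of 20 or its inverse and 1% of unchanged lists were called. In 200 simulations of the permutation test, a planted log2 difference of 1.5 was called in 77% of lists of 6 genes and 100% of lists of 20, and no difference in 7.5% and 3.5%. These used independent, normally distributed values and no adjustment over lists. Skewed counts such as those of distal peaks were not simulated. A planted replicate overlap of 39.9% was measured as 40.9%, random positions were found at a TSS in 5.88% of cases, and lists of random genes gave 0 replicate-specific calls. In 50 simulations each, a planted odds ratio of 0.5 on X and of 20 for CpG-rich promoters was called in 100%, and none in 2% and 0%.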

Results

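Acetylation of lysine 9 on histone H3 (H3K9ac), a mark found at active promoters, was mapped by chromatin immunoprecipitation and sequencing in forebrain of B6NCrl mouse embryos at embryonic day 12.5. All data belonged to 1 group with 2 biological replicates, each a pool of embryos of both sexes, 120 for replicate 1 and 68 for replicate 2, so the design holds no contrast between conditions. The deposited lists held 62538 peaks for replicate 1, 68111 for replicate 2, 88760 for the pooled alignments and 32778 in the replicated list, which the authors derived from the other lists. Replicated peaks on chromosomes numbered 32770 and covered 34.5 Mb, with a median width of 761 bp and a median fold enrichment of 4.73. Fold enrichment is the authors' own value for each peak and was used to rank or describe peaks inside a list. Some alternatives also used it as a threshold, with a fold enrichment of at least 4. Read depth is unknown, so the precision of a single peak cannot be given, and overlap between the replicates' own lists is the measure of replicate error.

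The strongest H3K9ac sites were shared by the embryo pools, whereas most weak sites were called in 1 pool only. In replicate 1, 48.0% of 62528 peaks overlapped a peak of replicate 2 by at least 50% of the shorter peak, and in replicate 2, 41.5% of 68101 peaks overlapped replicate 1. After circular shifts of 1 list along each chromosome the mean shares were 2.14% and 1.96%, with a highest share of 2.51% and 2.31% over 100 shifts. Shared sequence came to 22.6 Mb, which was 69.9% of the sequence covered in replicate 1 and 63.1% in replicate 2. With peaks ranked by fold enrichment and split into 10 equal bins, 100% of the top bin of replicate 1 overlapped replicate 2, against 14.5% of the bottom bin. In replicate 2 the corresponding shares were 99.99% and 12.8%. The replicated list was not the plain intersection of the replicates' lists. All 26825 pooled peaks that overlapped both lists were in it, and they made up 81.9% of it. The other 5945 replicated peaks overlapped replicate 1 alone (1691), replicate 2 alone (3896) or neither list (358), and were weaker, with a median fold enrichment of 3.09 against 6.15, and narrower, with a median width of 371 bp against 941 bp. Stricter lists raised the shares by over 1.5 times: among peaks with a −log10 q of at least 5, 90.6% of replicate 1 and 77.8% of replicate 2 overlapped the other replicate.

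**Figure D1:**
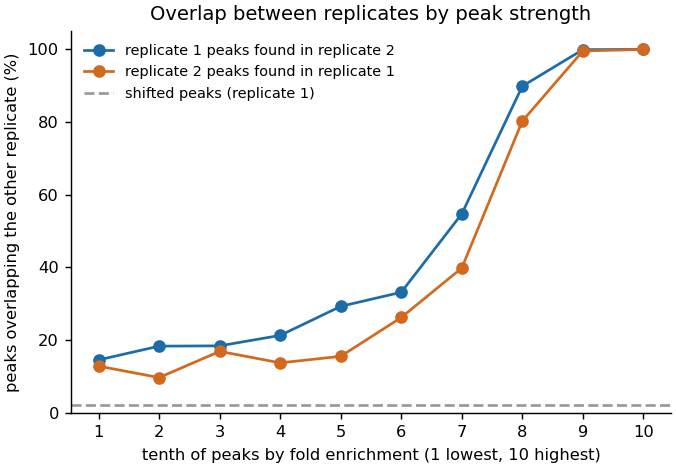
Share of each replicate's H3K9ac peaks that overlapped a peak of the other replicate (y axis, percent), in 10 equal bins of the peaks ranked on their own fold enrichment (x axis, lowest bin to highest), with the level after circular shifts as reference. The share went from 14.5% to 100% in replicate 1 and from 12.8% to 99.99% in replicate 2.

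H3K9ac lay mainly at transcription start sites (TSSs). The midpoint of 18560 replicated peaks (56.6%) was within 1 kb of an annotated TSS, 8.79 times the 6.45% of shifted peaks. Exons away from a TSS held 4.99% of peaks (3.41% shifted), introns 24.1% (40.2% shifted) and intergenic sequence 14.2% (49.99% shifted). Peaks at a TSS were wider and stronger than the 9970 distal peaks over 2.5 kb from every TSS: the median width was 1156 bp against 468 bp and the median fold enrichment 8.84 against 3.39. Of the TSS peaks 93.0% overlapped both replicates' lists, against 65.3% of the distal peaks. Each location differed from shifted peaks with a permutation p of 0.0198, the smallest that 100 shifts can give. The share at a TSS was 20.1% in the lowest of 10 bins of fold enrichment, 95.2% in the bin below the top and 93.1% in the top bin. The share at a TSS was lower in longer lists, 30.8% in the pooled list, and 41.0% and 38.3% in the own lists of replicates 1 and 2.

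The strongest replicated peak, with a fold enrichment of 45.6, covered a TSS and exon of Brsk1, which encodes a kinase of neuronal polarity, at chromosome 7: 4690149 to 4692143 (mm10). The second, of 44.5, lay over a TSS and exons of Arid1a, a subunit of the BAF chromatin remodelling complex, at chromosome 4: 133749995 to 133756131. The peak at chromosome 7: 73555945 to 73558654, with a fold enrichment of 43.2, covered a TSS and exon of the noncoding transcript 1810026B05Rik and lay over 1 kb from any protein-coding TSS. A peak of 43.2 at chromosome 2: 18044026 to 18051907 covered a TSS of Skida1. The fifth, of 41.8 and 12329 bp wide, covered a TSS and exons of Msi1, which encodes the RNA-binding protein Musashi-1 of neural progenitors, at chromosome 5: 115427436 to 115439764.

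Genes of the embryonic forebrain almost all carried H3K9ac at the TSS. Of 21911 protein-coding genes, 14105 (64.4%, exact 95% interval 63.7 to 65.0) had a replicated peak within 1 kb of an annotated TSS. Of these 14105 genes, 54 had a TSS peak in the own list of replicate 1 alone and 139 in that of replicate 2 alone. A further 14 had one in neither list. Marked members made up 26 of 26 dorsal telencephalon genes (such as Pax6, Emx2 and Lhx2), 24 of 24 ventral telencephalon genes (such as Dlx1, Dlx6 and Arx), and 25 of 25 genes of the diencephalon and hypothalamus (such as Lhx5, Lhx9 and Barhl2). All 28 neural progenitor genes, among them Sox1, Sox2 and Msi1, and all 28 early neuron genes, among them Insm1, Crmp1 and Myt1l, were marked. In the forebrain identity list 19 of 21 genes were marked (90.5%, exact 95% interval 69.6 to 98.8), without Hesx1 and Six6. Genes of the late neuron and synapse list were marked in 28 of 30 cases, including the glutamate receptor gene Grin2a and the postsynaptic scaffold gene Dlg4, and not at the neuropeptide genes Sst and Vip. Marked were also 29 of 31 patterning signal genes (not Bmp5 and Wnt3a), 75 of 75 ribosomal protein genes, 27 of 27 cell cycle genes and 27 of 27 genes of histone acetylation enzymes and readers.

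Each of these 11 lists was marked more often than other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 24 lists. Adjusted p was 3.65e-05 for dorsal and 8.36e-05 for ventral telencephalon, 5.15e-05 for diencephalon and hypothalamus, 2.58e-05 for neural progenitor, early neuron, cell cycle and histone acetylation genes, 6.50e-04 for late neuron, 4.34e-04 for patterning signals, 9.92e-14 for ribosomal proteins and 0.0148 for forebrain identity (odds ratio 5.26). In the own list of replicate 1 the forebrain identity share was 85.7% and its adjusted p 0.0912, and with 1 TSS per gene the histone acetylation share was 77.8% (0.0945). CpG-rich promoters were marked in 8242 of 8413 genes (98.0%, exact 95% interval 97.6 to 98.3), against 43.4% of the 13498 other genes. The odds ratio was 62.8, and the p of Fisher's exact test was below the smallest number the software holds. Among CpG-rich promoters alone none of the 11 lists passed the exact test (adjusted p of 0.464 for forebrain identity, 0.889 for patterning signals and 1 for the other 9). With 98.0% of that background marked, lists of these sizes had almost no room to pass as higher. The exact test there thus does not decide whether promoter class gave the calls. In lists with every member marked, members without a CpG-rich promoter were marked too, such as Pax6, Dlx1, Lhx9, Id2 and Myt1l. Such members were not tested as a group against the 43.4%.

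Genes of other organs, of blood and of the posterior body axis were marked less often. Of 39 HOX genes, which pattern the hindbrain, spinal cord and trunk, 6 were marked (15.4%, exact 95% interval 5.86 to 30.5): Hoxa1, Hoxa4, Hoxd8 and Hoxd13, and, outside the naming rule and listed after their values were seen, Hoxa7 and Hoxd1. Liver genes were marked in 4 of 24 cases (16.7%), at Vtn, Foxa3, Rbp4 and Trf, and not at Alb, Afp or Ahsg. The marked stretches at Vtn, Foxa3 and Trf also reached the TSS of a neighbouring gene, Sarm1, Sympk and Gm20425. Pluripotency and germline genes were marked in 5 of 24 cases (20.8%), at Utf1, Dazl, Esrrb, Prm1 and Tdgf1. Prm1 and Tdgf1, like the liver gene Trf, had a TSS peak in the own list of replicate 2 and not in that of replicate 1. Muscle genes were marked in 6 of 24 cases (25%), including Mef2c and Des and not Acta1, Actc1 or Gata4. Of 22 erythroid genes 6 were marked (27.3%), including the transferrin receptor gene Tfrc and the transcription factor gene Klf1, and not Alas2 or Epb42. Of 22 microglia and myeloid genes 6 were marked (27.3%), including Sall1, which is also a developmental transcription factor gene, Runx1 and Irf8, and not Aif1, C1qa or C1qb. Of 1092 olfactory receptor genes 1 was marked, Olfr94 (0.0916%).

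Fisher's exact test gave an adjusted p of 3.20e-09 for HOX, 1.31e-05 for liver, 3.92e-05 for pluripotency and germline, 2.27e-04 for muscle, and 7.03e-04 for each of erythroid and microglia, while for olfactory receptors it was below the smallest number the software holds. The other 6 lists did not pass Fisher's exact test: astrocyte and oligodendrocyte (12 of 24, adjusted p = 0.228), midbrain, hindbrain and spinal cord (19 of 29, 1), retina and eye (10 of 22, 0.0950), choroid plexus (11 of 19, 0.661), endothelial (11 of 24, 0.102) and mesenchyme (18 of 25, 0.581). Marked members of these included Pdgfra, Nkx2-2, Lmx1b, Egr2, Otx2, Foxj1, Fli1, Sox17 and Foxc1, and unmarked ones Aqp4, Chat, Crx, Aqp1, Cdh5 and Dcn. Sox17 had a TSS peak in the own list of replicate 2 and not in that of replicate 1. By the same exact test, the microglia share was 50% in the own list of replicate 1 (adjusted p = 0.211) and 63.6% in the pooled list (0.779), and the muscle share was 50% in the pooled list (0.101). The midbrain, hindbrain and spinal cord share changed direction, from 41.4% with a fold enrichment of at least 4 (lower, exact test, adjusted p = 0.0396) to 89.7% in the pooled list (higher, 0.0208). With a −log10 q of at least 5, astrocyte and oligodendrocyte (0.0408), retina (0.0167) and endothelial genes (0.00636) passed as lower, as they did with a fold enrichment of at least 4. Among CpG-rich promoters alone the exact test left HOX (30.0% marked, adjusted p = 9.22e-19) and pluripotency and germline genes (28.6%, 7.32e-07) lower. By the same exact test midbrain, hindbrain and spinal cord (76.5%, 0.00234) and retina genes (66.7%, 0.0321) were lower too. The erythroid (50%, exact test, 0.177), microglia and muscle calls ended, the last 2 with every such gene marked (3 and 1 genes, adjusted p of 1 each). The liver and olfactory receptor lists held no gene with a CpG-rich promoter. They could not be tested there, so their lower shares were not separated from promoter class.

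**Figure D2:**
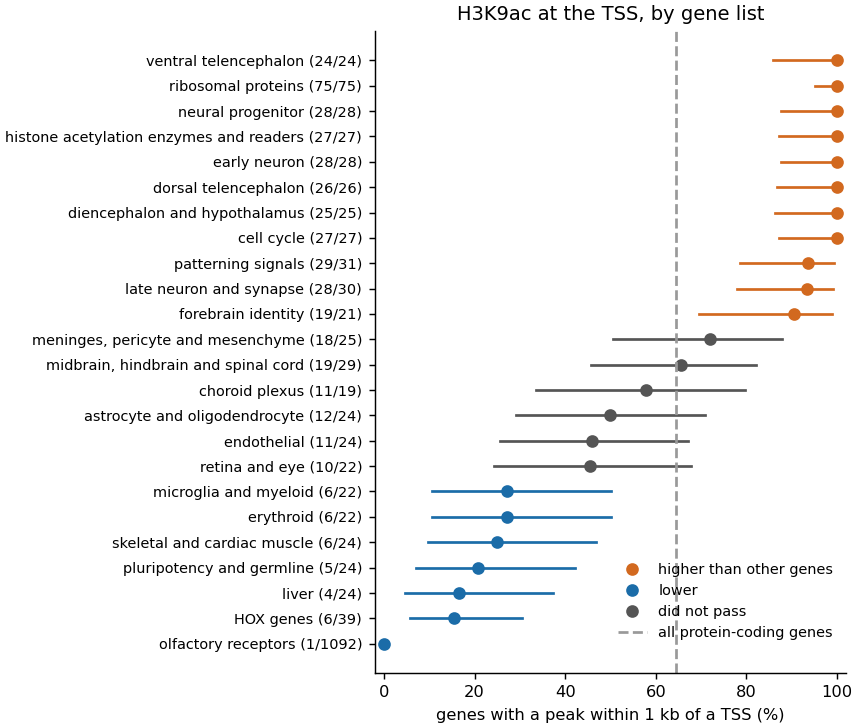
Share of genes with a replicated H3K9ac peak within 1 kb of a TSS (x axis, percent) for each of the 24 gene lists (y axis), with points for the shares and bars for exact 95% intervals, and the share of all protein-coding genes, 64.4%, as reference. The dorsal, ventral and progenitor lists sit at 100%, HOX genes at 15.4% and olfactory receptors at 0.0916%.

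Among marked genes, the longest stretches of H3K9ac lay at transcription factor genes of the forebrain. A domain was a run of replicated peaks joined over gaps of up to 1 kb that reached the TSS window. Forebrain identity genes had a median domain of 13954 bp (19 genes), against 1876 bp for other marked genes. Medians were 7743 bp for ventral telencephalon, 5594 bp for neural progenitor, 5056 bp for dorsal telencephalon, 3600 bp for patterning signal, 3443 bp for early neuron, 2812 bp for histone acetylation, 2699 bp for cell cycle and 2587 bp for ribosomal protein genes. Domains were shorter at the 6 marked HOX genes (584.5 bp), the 5 pluripotency and germline genes (664 bp), the 6 erythroid genes (905.5 bp), the 18 mesenchyme genes (953.5 bp) and the 19 midbrain, hindbrain and spinal cord genes (1057 bp).

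The difference in mean log2 domain length was 2.82 for forebrain identity, 1.81 for ventral telencephalon, 1.57 for dorsal telencephalon, 1.55 for neural progenitor, 0.86 for early neuron and 0.56 for ribosomal protein genes, each with an adjusted p of 7.67e-05 from a raw p of 2.0e-05, the smallest that 100000 permutations can give. It was 0.73 for cell cycle and 0.72 for patterning signals (permutation test, adjusted p of 1.84e-04 each) and 0.54 for histone acetylation genes (0.00460). It was −1.72 for pluripotency and germline and −1.65 for HOX genes (adjusted p of 1.84e-04 each by permutation), −0.90 for erythroid (0.0312), −0.69 for midbrain, hindbrain and spinal cord (0.00343) and −0.56 for mesenchyme (0.0202). The other 9 of 23 lists did not pass: diencephalon and hypothalamus (0.29, adjusted p = 0.136), late neuron (−0.03, 0.856), astrocyte and oligodendrocyte (−0.51, 0.0799), retina and eye (−0.58, 0.0732), choroid plexus (−0.06, 0.856), endothelial (−0.43, 0.148), microglia (−0.55, 0.170), muscle (−0.63, 0.130) and liver (−0.45, 0.339), the last 4 with 4 to 11 marked genes, all by permutation tests. In the own list of replicate 1 the erythroid and the pluripotency and germline calls ended (adjusted p of 0.123 and 0.0607), and the histone acetylation call ended when covered sequence within 5 kb of the TSS was measured instead (0.266). The erythroid call also ended in the pooled list (permutation test, 0.0597), with no gaps joined (0.0604), with 1 TSS per gene (0.168) and in domains of 1 protein-coding gene (0.0586). The mesenchyme call ended in the pooled list (permutation test, 0.929), with gaps of up to 3 kb (0.0537), among CpG-rich promoters (0.666), by covered sequence within 5 kb (0.0656), with 1 TSS per gene (0.168) and in domains of 1 protein-coding gene (0.0601). Astrocyte and oligodendrocyte, retina, endothelial, microglia and muscle genes passed as shorter in the own list of each replicate (highest adjusted p by permutation 0.0310), choroid plexus (0.0494) and liver (0.0496) in that of replicate 1, and diencephalon and hypothalamus as longer in that of replicate 2 (0.0418). The latter list also passed as longer in the pooled list (a difference of 0.743, permutation test, adjusted p = 8.80e-04), with gaps of up to 3 kb (0.602, 0.0103) and in domains of 1 protein-coding gene (0.404, 0.0471). With no gaps joined its difference was −0.105 (permutation test, 0.525). In the own lists of replicates 1 and 2 the forebrain identity difference was 3.07 and 2.62.

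**Figure D3:**
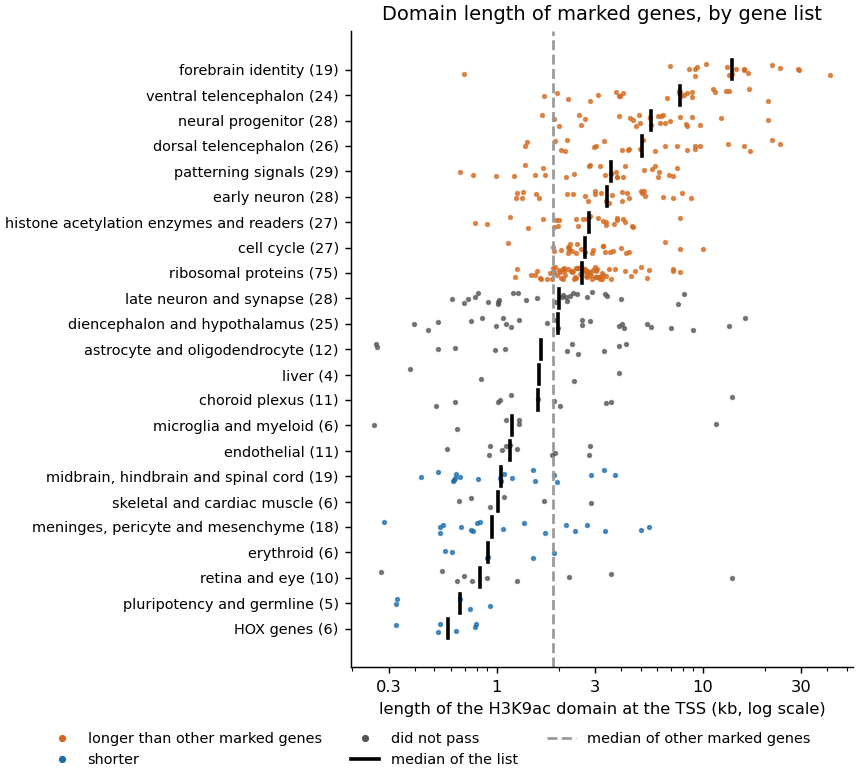
Length of the H3K9ac domain at the TSS (x axis, kb, log scale) of each marked gene, by gene list (y axis, with the number of marked genes), where points are genes, black bars list medians and the dashed line the median of other marked genes. Forebrain identity genes have a median of 13954 bp and HOX genes of 584.5 bp.

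With gaps of up to 1 kb joined, the longest domain of all protein-coding genes lay at Nr2f1, a nuclear receptor gene of cortical area patterning, over 41.4 kb of chromosome 13 (78169683 to 78211115), with 37.9 kb in replicate 1 and 31.5 kb in replicate 2. Pou3f3, a POU-domain factor gene, had 31.2 kb (31.1 and 31.8 kb in the replicates) at chromosome 1: 42683492 to 42714660. Foxg1, which encodes a transcription factor needed for telencephalon growth, had 29.5 kb (22.8 and 29.4 kb) at chromosome 12: 49372781 to 49402254, a domain that spans the whole annotated gene and also reaches the predicted gene Gm43517. Nr2f2 had 29.1 kb (29.0 and 29.0 kb), Lhx2 23.8 kb (15.3 and 25.05 kb), Pax6 21.8 kb (23.1 and 21.5 kb), Sox2 20.8 kb (19.0 and 25.03 kb) and Meis2 20.7 kb (20.4 and 20.6 kb). Others of the 20 longest were Bahcc1 (20.2 kb; 20.7 and 20.2 kb in the replicates), Mn1 (18.0 kb; 18.0 and 20.6 kb), Nfib (17.1 kb; 16.5 and 16.9 kb), Dlx6 (16.8 kb; 17.1 and 15.7 kb), Otx1 (16.5 kb; 16.3 and 16.4 kb), Pou3f2 (16.1 kb; 14.9 and 16.1 kb), Emx2 (15.9 kb; 15.5 and 17.6 kb) and Six3 (15.8 kb; 14.2 and 15.5 kb). Skida1, Mllt10 and A930004D18Rik shared a domain of 20.8 kb, which neither replicate's own list joined for all 3. Skida1 had 20.5 kb in replicate 1 and 13.5 kb in replicate 2, Mllt10 20.5 and 5.84 kb, and A930004D18Rik 3.61 and 8.55 kb. Outside these, Otx2 had 14.0 kb (9.14 and 13.9 kb in the replicates), Arx 13.4 kb (11.3 and 15.7 kb), Lhx5 13.4 kb (13.1 and 16.5 kb), Dlx1 13.0 kb (13.8 and 13.2 kb) and Ccnd2, a cyclin gene of cycling progenitors, 10.04 kb (7.07 and 4.28 kb).

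Across the 13994 genes marked in both replicates' own lists, domain lengths in the replicates had a Spearman correlation of 0.848 across genes, which are not independent replicates, and 78.7% of genes lay within 1.5-fold. These lengths and their order depended on joining: with no gaps joined, the TSS domain was 7.45 kb at Nr2f1, 4.26 kb at Pou3f3, 5.53 kb at Foxg1 and 2.14 kb at Sox2, and longer at Meis2 (16.1 kb), Lhx2 (15.5 kb), Otx1 (13.2 kb) and Msi1 (12.3 kb). With gaps of up to 3 kb joined, Nr2f2 (47.3 kb) exceeded Nr2f1 (41.4 kb). The region of Foxg1 from 49355000 to 49420000 on chromosome 12 held 14 peaks in the own list of replicate 1, 17 in that of replicate 2, and 14 in the replicated list. The longer HOXA region, chromosome 6 from 52140000 to 52280000, held 3, 6 and 3, and 7 in the pooled list.

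**Figure D4:**
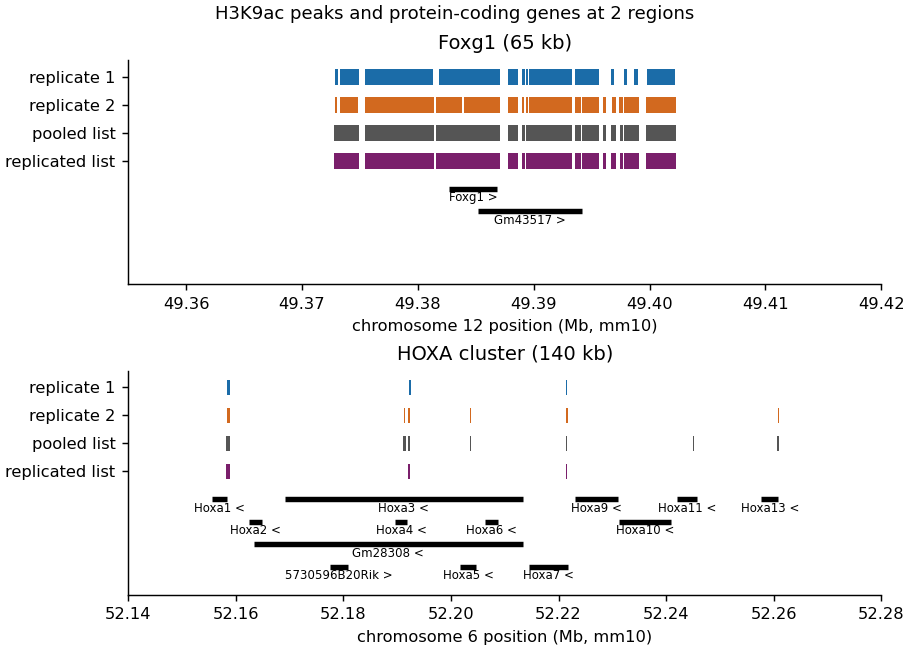
H3K9ac peaks (boxes, drawn to scale, 1 line per list) and protein-coding genes (black bars, with strand) at Foxg1 on chromosome 12 and at the HOXA cluster on chromosome 6 (x axes, position in Mb on mm10). The Foxg1 region holds 14 replicated peaks and the HOXA region 3.

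Distal H3K9ac peaks gathered around neural progenitor genes, whereas the excess at forebrain identity genes lay partly inside their long TSS domains. Marked forebrain identity genes had a mean of 5.32 distal replicated peaks within 100 kb of the TSS and marked neural progenitor genes 5.29, against 1.80 for other marked genes. Over all marked members, forebrain identity genes had from 0 (Fezf2 and Rax) to 13 such peaks (Nr2e1). Neural progenitor genes had from 0 (Prom1) to 16 (Notch1). Among the members named for their long domains, forebrain identity genes had from 2 (Pax6, Otx1 and Otx2) to 9 such peaks (Foxg1, Nr2f1 and Six3). Of the neural progenitor genes so named, Id2 had 1, Sox2 6, Sox1 8 and Msi1 11. The permutation test gave an adjusted p of 9.20e-04 for both lists and passed no other of 23 lists, with means of 3.31 for dorsal telencephalon (adjusted p = 0.152), 3.00 for ventral telencephalon (0.291), 2.68 for diencephalon and hypothalamus (0.351), 1.89 for early neuron (0.928) and 0.333 for HOX genes (0.341). Means above 2.6 were also found for erythroid (4.17, permutation test, adjusted p = 0.333), muscle (3.67, 0.351), cell cycle (2.93, 0.291) and liver genes (2.75, 0.699). The other 12 lists had means from 1.11 to 2.58. The most distal peaks lay near Flrt1 and Gse1 (30 each), G430095P16Rik (29), Gins2 (27) and 4933428G20Rik (26). Of these Flrt1, a gene of a cell adhesion protein, had no replicated TSS peak. It had one in the own list of each replicate, with domains of 0.18 kb in replicate 1 and 1.899 kb in replicate 2. Distal peaks were not kept apart from TSS domains. With only distal peaks outside every domain that reaches a protein-coding TSS, an alternative chosen after seeing the data, the neural progenitor mean was 4.68 against 1.68 for other marked genes (permutation test, adjusted p = 0.00138). The forebrain identity mean was then 3.21 and its call ended (permutation test, 0.358), with 0 such peaks at Foxg1, 2 at Nr2f1 and 7 at Six3. Other members lost none, such as Nr2f2 (6 of 6 kept) and Otx2 (2 of 2). The neural progenitor gene Msi1 had 11 such peaks. In permutation tests the forebrain identity call also ended in the pooled list (adjusted p = 0.471) and with a window of 250 kb (0.318). Dorsal and ventral telencephalon passed when only replicated peaks with a −log10 q of at least 5 were used (0.0140 and 0.0123), and in the own list of replicate 2 HOX genes passed as lower (2.40e-04).

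Few genes were marked in 1 embryo pool alone. A TSS peak was found in the own list of replicate 1 alone at 391 genes and of replicate 2 alone at 596, against 13994 in both. These were short stretches, with medians of 216 bp in replicate 1 alone and 245 bp in replicate 2 alone, against 1736 bp and 1868 bp at the shared genes. The longest in replicate 1 alone were 4930415O20Rik (5.04 kb), Slc35g3 (4.85 kb), Tmem102 (4.78 kb), and Gm21983 and Mia (2.56 kb each). In replicate 2 alone they were Gm28035 (5.15 kb), AC141477.1 (3.598 kb), Nup160 (3.11 kb), Mip (2.59 kb) and Gdf15 (2.57 kb). Microglia and myeloid genes numbered 6 in replicate 1 alone and 4 in replicate 2 alone, and astrocyte and oligodendrocyte genes 0 and 4. Fisher's exact test, two-sided, of list membership between the genes of replicate 1 alone and those of replicate 2 alone called 0 of 24 lists, with an adjusted p of 1 for each and a lowest unadjusted p of 0.157, so 0 also passed without adjustment. It compares these libraries, not conditions, and does not ask whether a list is frequent among the genes of both sets together. Lists with 0 genes in both sets, such as dorsal telencephalon and neural progenitor, could not pass. The others held at most 6 genes in a set, so 0 calls do not show that the pools were alike in cell types. With a −log10 q of at least 5 in the replicate that had the peak, the counts were 16 and 59 genes.

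Genes on chromosome X carried H3K9ac at the TSS less often than autosomal genes. Of 948 X-linked protein-coding genes 444 were marked (46.8%, exact 95% interval 43.6 to 50.1), against 65.7% of 20780 autosomal genes (odds ratio 0.459, p = 3.38e-31, Fisher's exact test, two-sided). Arx, a homeobox gene of the ventral telencephalon, was among the marked X-linked genes, and the choroid plexus gene Cldn2 and the erythroid gene Alas2 among the unmarked. Among genes with a CpG-rich promoter the odds ratio was 0.479 and did not pass (exact p = 0.0892).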

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

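The tests of developmental gene class and of promoter composition as the whole cause, in non-neural and posterior lists and on X, were chosen after the results were seen, and the other tests before.

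Of the 55977 pooled peaks left out of the replicated list, which the main comparisons do not use, 15.7% had the midpoint at a TSS, against 6.48% of shifted peaks (highest of 100 shifts 7.26%; permutation p = 0.0198, the smallest that 100 shifts can give). They were weak and narrow, with a median fold enrichment of 2.52 and a median width of 222 bp, and the pooled list added a TSS peak at 879 genes, among them 10 HOX, 8 microglia and myeloid, 7 midbrain, hindbrain and spinal cord and 6 muscle genes. The replicated list also held 8 peaks on 4 unplaced scaffolds, with fold enrichments from 1.53 to 8.48.

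Domains at forebrain identity genes were longer than at other marked genes, by 2.82 in mean log2 length. The values argue against promoter composition or joining across neighbours as the whole cause: the difference was 2.70 among CpG-rich promoters (8 genes, permutation p of 2.0e-05, the smallest possible) and 2.89 among domains that reach 1 protein-coding gene (16 genes, the same p). Being a developmental transcription factor gene was not enough, since the 23 marked transcription factor genes of the HOX and the midbrain, hindbrain and spinal cord lists had shorter domains than other marked genes (−0.92, the same p). Both lists had already been called shorter, so the direction of this difference was known and its p is no separate support. With 1 group no biological explanation was tested.

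Some genes of non-neural and posterior lists carried a TSS peak. Of 209 members of 8 such lists 76 were marked (36.4%), below the 127.5 (61.0%) expected from the shares of CpG-rich and other promoters. The two-sided permutation p was 2.0e-05, the smallest possible, but the test was chosen once this count was known and is no separate support. Promoter class alone thus did not give the count, and CpG content inside a class was not matched. Whether composition contributes stays open, because a count not above the expected one (one-sided permutation p of 1 for an excess) leaves room for it. Whether blood, vessel and connective tissue cells in the dissection added marked genes stays open: without a CpG-rich promoter, 33.8% of 74 genes of those cell types were marked against 19.1% of 47 muscle and liver genes (odds ratio 2.15, p = 0.0986, Fisher's exact test). The globin genes, among the most abundant transcripts of erythroid cells, had no replicated TSS peak. Near-identical copies such as Hba-a1 and Hba-a2 may lose reads in alignment, which was not measured. Hba-x, Hbb-bh1 and Hbb-y, which are not such copies, were unmarked too, so that loss would not account for all globin genes.

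Fewer genes on X than on autosomes had a TSS peak, by 18.9 percentage points. CpG-rich promoters made up 18.2% of X-linked and 39.6% of autosomal genes, and class shares alone gave an expected 54.3% on X against 46.8% observed. X was also lower among other promoters (35.9% against 44.5%, odds ratio 0.697, p = 2.51e-06, Fisher's exact test). CpG content still varies inside that class, so this does not settle whether composition is the whole cause. The values argue against copy-rich gene families as the whole cause, since named genes from small families differed by 14.6 points (65.3% against 79.9%, p = 3.68e-09, Fisher's exact test). Among CpG-rich promoters the gap was 2.07 points (96.0% against 98.0%, exact p = 0.0892), a share too near 100% to settle how much composition contributes. The pools held both sexes, so no explanation from X inactivation was tested.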

How the results depend on the processing

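The peak list restricted to peaks in both own lists, the class of genes with any CpG-rich TSS, X among CpG-rich promoters, domains of 1 gene or without shared list members, and distal peaks outside TSS domains were chosen after seeing the data.

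Replicate overlap moved with each setting: for replicate 1 peaks 52.7% with 1 bp, 43.1% with 75% of the shorter peak, 34.4% with 50% of both, 90.6% at a −log10 q of 5, 82.4% at a fold of 4 and 47.2% with equal numbers of top peaks, and for replicate 2 peaks 45.9%, 37.3%, 31.6%, 77.8%, 81.5% and 44.2%. Replicated peaks in both own lists were 82.3% with 1 bp and 56.7% with 50% of both. The TSS location share lay at 38.3% and 41.0% without replicate 1 and 2. Marked protein-coding genes were 62.9% at a −log10 q of 5, 60.9% at a fold of 4, 65.7% to 66.6% leaving out a replicate, 68.4% in the pooled list, 63.3% with peaks in both own lists, 65.2% with 2 kb and 60.6% with 1 TSS per gene.

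Lists called for TSS peaks were 21 at a −log10 q of 5 and 22 at a fold of 4. They ranged from 16 to 18 without a replicate and were 4 among CpG-rich promoters (2 shared with the main 18) and 3 with any CpG-rich TSS (2 shared). List shares turned to the other side of the background, at a −log10 q of 5 midbrain (44.8%), mesenchyme (56%); at a fold of 4 midbrain (41.4%), mesenchyme (48%); in the pooled list astrocyte (70.8%), choroid plexus (73.7%); with peaks in both own lists midbrain (58.6%); with 500 bp midbrain (58.6%); with 1 TSS per gene midbrain (55.2%), mesenchyme (60%); among CpG-rich promoters forebrain identity (88.9%), astrocyte (100%), midbrain (76.5%), choroid plexus (100%), microglia (100%), mesenchyme (87.5%), muscle (100%), patterning signals (95.5%); without receptor genes midbrain (65.5%); with any CpG-rich TSS forebrain identity (93.3%), astrocyte (100%), midbrain (71.4%), choroid plexus (100%), microglia (100%), mesenchyme (91.7%), liver (100%), patterning signals (95.8%). Leaving out replicates 1 and 2 in turn gave astrocyte (66.7% and 50%), choroid plexus (68.4% and 68.4%), midbrain (75.9% and 62.1%), of which at least 1 value turned. The background of 98.0% among CpG-rich promoters leaves little room above it. Of these 31 turned shares 3 passed, all midbrain (a fold of 4 and both CpG classes). Of the other list shares 213 kept direction and side of the threshold, 15 newly passed and 26 no longer did.

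Lists called for domain length were 21 and 20 without replicate 1 and 2 (14 and 12 shared with the main 14). Over all settings 212 list differences kept direction and side, 30 newly passed, 13 no longer did and 12 turned, none of which passed: in the pooled list late neuron (0.106); with no gap diencephalon (−0.105); with a 3 kb gap late neuron (0.0284), choroid plexus (0.141); among CpG-rich promoters retina (0.0105), choroid plexus (0.315), microglia (0.00593); in domains of 1 gene late neuron (0.0792), choroid plexus (0.0517); with any CpG-rich TSS astrocyte (0.0403), choroid plexus (0.269); without replicate 1 and 2 late neuron (0.00761 and −0.202). Lists called for distal peaks were 4 at a −log10 q of 5, 4 at a fold of 4, 2 to 4 leaving out a replicate, 5 within 50 kb, 1 within 250 kb, 1 outside TSS domains and 5 when matched on neighbouring TSSs. Of distal differences 227 kept direction and side, 13 newly passed, 3 no longer did and 30 turned, none of which passed: at a −log10 q of 5 pluripotency (−0.268); at a fold of 4 astrocyte (−0.337), midbrain (0.103), ribosomal protein (−0.0672), histone acetylation (0.1498); in the pooled list diencephalon (−0.930), early neuron (−0.334), retina (0.0982), choroid plexus (−0.154), histone acetylation (0.373); with peaks in both own lists mesenchyme (0.220); within 50 kb midbrain (0.00392), retina (0.309), endothelial (−0.0727), histone acetylation (0.109); within 250 kb choroid plexus (−0.758), endothelial (−0.485), histone acetylation (0.219); over 5 kb from a TSS midbrain (0.279), retina (0.0574); when matched on neighbouring TSSs midbrain (0.356), mesenchyme (0.470); outside TSS domains microglia (−0.187); without replicate 1 and 2, of which 1 value turned, endothelial (−1.08 and 1.29), pluripotency (−0.0637 and 0.958), early neuron (0.645 and −0.0659), midbrain (−0.692 and 0.737), choroid plexus (0.845 and −0.401), mesenchyme (−0.464 and 0.0137), histone acetylation (−0.131 and 0.329). Genes marked in replicate 1 alone were 211, and in replicate 2 alone 374, when no peak within 5 kb was allowed in the other, and 16 and 59 at a −log10 q of 5, with 0 lists called throughout. The X odds ratio was 0.421 to 0.450 leaving out a replicate, 0.479 (exact p = 0.0892) among CpG-rich promoters and 0.561 (exact p = 0.145) with any CpG-rich TSS. The CpG odds ratio was 58.4 to 69.8 leaving out a replicate. Of single-gene domain lengths 1022 stayed within the replicate spread and 427 moved. Except where fewer genes or peaks entered by construction, the cause was not tested. Read depth is unknown, and its effect on weak peaks was not measured.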

Other observations

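The sequence word test was set before its result was seen, and the other values here were chosen after the data were seen.

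The 3 longest H3K9ac domains without a protein-coding TSS held the copies of a microRNA gene of neural development. Of 24735 domains 10380 (42.0%) reached no protein-coding TSS, with a median of 0.514 kb against 1.69 kb for the rest. These 3 held the copies of the microRNA gene miR-9, a regulator of neural progenitors: Mir9-1 in 34.7 kb of chromosome 3 (88197663 to 88232368), Mir9-3 in 32.3 kb of chromosome 7 (79495623 to 79527919) and Mir9-2 in 29.8 kb of chromosome 13 (83712753 to 83742577). The domain of Mir9-1 measured 35.1 kb in replicate 1 and 34.5 kb in replicate 2. Domains at the copies of the neuronal microRNA gene miR-124 measured 12.1 kb (Mir124a-2), 9.94 kb (Mir124a-1) and 8.82 kb (Mir124a-3), and that of Mir125b-1 12.02 kb. Of 2202 annotated microRNA genes 239 (10.9%) lay in a domain, 47 of them in one without a protein-coding TSS and 192 in one that reaches such a TSS. Of the 20 longest domains without a protein-coding TSS 9 held a microRNA gene and 11 none, and enrichment was not tested. A domain of 12.8 kb lay inside Notch1 and reached no protein-coding TSS.

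CpG-rich promoters without a replicated H3K9ac peak were few and included genes of other lineages. Of 8413 such genes 171 (2.03%) had no replicated TSS peak, and 66 of these had a pooled one. They included 14 of the 20 HOX genes with a CpG-rich promoter, 15 genes of meiosis and germ cells such as Sycp1, Sycp3, Dmc1, Ddx4 and Mael, and transcription factor genes of other tissues such as Cdx1, Cdx2, Pax3, Pax9 and Tlx1. The last 2 groups were picked from the 171 genes after these were seen. How many CpG-rich genes of those groups were marked was not counted, and enrichment was not tested. Of those named, Cdx1 had a TSS peak in both replicates' own lists and the pooled list, Dmc1 in replicate 1 and pooled, Pax3 in replicate 2 and pooled and Tlx1 in pooled alone, and the others in none. A further 47 had only numbered or clone-based names. Some unmarked genes had paired names, such as Srp54b and Srp54c or Plac9a and Plac9b. Reads from similar copies may be lost in alignment, also in large families and pseudogenes, and this was not measured. By gene family, all 49 Mrpl and 29 Mrps mitochondrial ribosome genes, 30 Med mediator genes and 35 Vps sorting genes were marked, and 0 of 22 clustered protocadherin Pcdhb, 42 Defb, 57 Krtap and 34 Rhox genes, in 10 families with every member marked and 16 with none among 141 families of at least 15 names. A TSS peak was present at 14.6% of 5854 lincRNA genes and 1.35% of 9940 processed pseudogenes. In these pools of both sexes the female-expressed noncoding gene Xist had a domain of 1.89 kb on X, and 3 of 183 genes on Y were marked, Ddx3y, Kdm5d and Uty.

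A hypothesis was that distal peaks hold binding sites of transcription factors active in embryonic forebrain. Of 6 words assigned to neural factors 2 were in the top 5% of words of equal base composition by enrichment over flanking sequence. They were TAATTA (rank 1 of 36) and ACAAAG (rank 23 of 492). Of 4 words assigned to other lineages (AGATAA, CTATTT, CAAAGT and GTAAAC) 0 were. Which factors bind each word was not tested, so the sets may not be separate by lineage. The ranks were relative: TAATTA was less frequent in distal peaks than in the flanks (ratio 0.776), as were the other words of its composition, and ACAAAG had a ratio of 1.09. This lies between the outcomes set beforehand and leaves the hypothesis open. The most enriched words all held CG, such as ATCGCG at 3.28-fold, and words were not matched on CG content, so base composition may also rank them.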
